A study of Medicago truncatula with 6 samples.

How the data were processed

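Nodules of Medicago truncatula lin-5 inoculated with Sinorhizobium meliloti were collected in liquid nitrogen at 2 or 4 wpi, per the labels' protocols. RNA was extracted with RNAiso Plus, and cDNA was primed with random hexamers, with the second strand marked by dUTP, per the labels' protocols. CASAVA is the only tool named in the submitters' processing notes, with no version. The aligner, counter, genome build, annotation and use of strand in counting are not given in the sources used here. Genes that share reads with near-identical copies, and overlapping or antisense genes, are therefore uncertain.

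The deposited table holds RPKM values made by the authors, with 1 column for each of the 6 libraries and 52847 rows, of which 51519 carry MTR identifiers and 1328 ENSRNA identifiers. Groups and replicate numbers came from the sample titles and source names. No gene names or descriptions were given. None of the identifiers matched the RefSeq table of assembly MtrunA17r5.0-ANR (0 matches), so none could be named from it.

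Because RPKM values of a gene are whole multiples of the worth of 1 read, the total of each library and the length of each gene were recovered from the steps. Whether these totals count reads or fragments is not known. Lengths were resolved for 26000 of 26330 genes with at least 3 values above 0 (98.7%), where fewer than 0.001 chance fits were expected. Among resolved genes with at most 400 reads, 100% of values above 0 lay within 0.02 of a whole number. As lengths were chosen to give whole numbers, this share describes the fit and is not an independent check. The method was tested on 29790 simulated genes with whole reads. Their lengths were those recovered from the data, or a fixed length where none was resolved. This run cannot show that the deposited values follow the same model. The length was exact for 99.1% of resolved simulated genes with at least 20 reads. A length can come out too short by a factor of 2 where all reads of a gene are even. This befell 0.744% of those simulated genes. Floors of 3 reads cover counting error only.

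Genes with at least 1 RPKM in at least 3 libraries (20667 of 29790 above 0 in any library) were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(RPKM + 1) for 4 wpi minus 2 wpi, without a replicate block. Tests were 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. At an unadjusted p under 0.05, 11279 genes passed. Reads were also simulated for 15000 genes, 200 of them changed, at a dispersion of 0.03. Of these genes 14788 were tested. The fit recovered 62.9% of 2-fold and 100% of 4-fold changes, with 10 false calls. A far larger share of genes was called in the data, so these rates need not carry over. No pair of libraries agreed within sampling noise. Single values per library were compared with an exact permutation test of 3 against 3, whose smallest p is 0.1. Recovery and other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.

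The design, the rule for named genes and most alternatives were fixed before the data were examined. With no gene names, the rule was to print the 2 identifiers with the largest rise and the 2 with the largest fall. These had to pass the test, have a mean of at least 5 RPKM in the higher group and not overlap between groups. The same rule left gene lists untested. The 35 lists defined by words in gene descriptions were accordingly not tested. A list of 30 identifiers, also fixed beforehand, was tested as a departure from that rule, since it needs no description. The pairing of these identifiers with nodulation genes rests on general knowledge. For 12 of them the reference holds a single gene of the listed name, and 11 of these lie on the chromosome whose number the identifier carries. The other match was a mitochondrial gene that shares its symbol with the listed gene. The locus listed as LIN was not among those 12, and giving its values by name departed from the rule for named genes.

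Alternatives were other pseudocounts (0.1, 0.5 and 5), no filter or at least 5 RPKM, 3 scalings, 2 variance settings, a replicate block, a 2-fold threshold, other gene set tests and leaving out each library in turn. Added after seeing the data were voom on recovered reads, removal of the 100 most abundant genes from the total, removal of the trend of change with gene length, and 2-fold counts without 2 wpi replicate 2. The share held by the 100 most abundant genes was also added then, as were the groupings by length and neighbouring identifiers.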

Results

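RNA was sequenced from nodules of the Medicago truncatula material named lin-5, collected 2 or 4 weeks post inoculation (wpi) with a Sinorhizobium meliloti strain carrying a nifH reporter. Medicago truncatula is a legume whose root nodules house nitrogen-fixing rhizobia. Each time point had 3 libraries. The labels do not say whether these came from separate plants or batches, so p-values measure the spread between these libraries, which may be technical. Expression was given as RPKM (read numbers scaled by gene length and by the library total). The totals behind the values, recovered from their steps, were 19690567, 19904319 and 19013770 in replicates 1, 2 and 3 at 2 wpi and 20467040, 21110718 and 20298483 at 4 wpi. A single read in a gene of 1000 bp was worth about 0.0498 RPKM. The study asked how expression differs between late and early lin-5 nodules, and the single comparison was 4 wpi against 2 wpi. The lesion carried by lin-5 is not described in the labels, and no locus was taken here as its target. A locus written down beforehand under the name LIN was tested as 1 of the 30 listed identifiers described below. It fell from 2.25 to 0.959 RPKM (log2 change -0.71, limma adjusted p = 0.0189). Its 4 wpi mean lay under the 1 RPKM used as the filter, and falls were common, as 6437 of 20667 tested genes were called lower. Giving this locus by name departed from the rule for named genes. Its pairing with that name rests on general knowledge and could not be checked by chromosome.

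Many genes differed between the time points, and the largest differences were rises. Of 20667 genes tested, 9829 (47.6%) passed the test, 3392 of them higher and 6437 lower at 4 wpi. Rises were larger than falls, with a median log2 change of 0.98 among genes that rose and -0.72 among genes that fell. The log2 change was above 3 in 464 called genes and below -3 in 44. Changes of at least 2-fold numbered 3536, with 1669 rises and 1867 falls. Among abundant transcripts, 216 called genes with a mean of at least 100 RPKM at 4 wpi had a log2 change of at least 3, whereas 19 with a mean of at least 100 RPKM at 2 wpi had one of -2 or less. Values of the 3 libraries at each time did not overlap in 12258 genes (59.3%), against 10% given by chance.

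**Figure D1:**
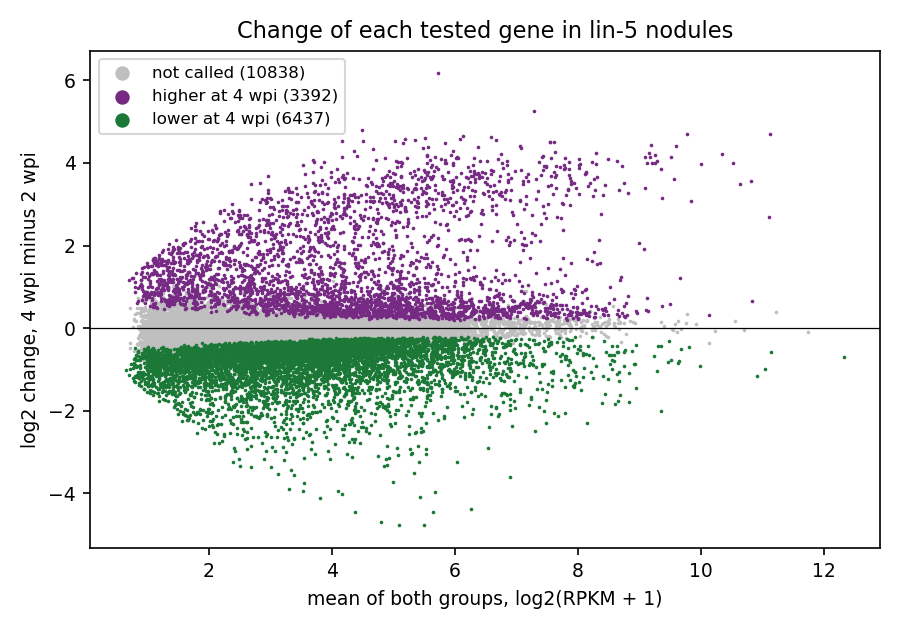
Log2 change (4 wpi minus 2 wpi) against the log2 of mean RPKM + 1 for each tested gene, with 3392 genes called higher (purple), 6437 called lower (green) and the others in grey. Called changes run from -4.77 to 6.17.

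The split by direction depended on scaling. The median log2 change of all tested genes was -0.16 in the RPKM values, -0.34 after rescaling to a common sum (TPM) and about 0 with median-ratio size factors. Higher genes made up 34.5% of calls in the RPKM values, 22% with TPM (2566 higher and 9098 lower) and 51.5% with median-ratio factors (4749 higher and 4464 lower). Relative to the median of all genes in the RPKM values, 1893 called genes were at least 2-fold higher and 1359 at least 2-fold lower. Differences were tested with limma on log2(RPKM + 1), 2-sided, with Benjamini-Hochberg adjustment. Fold changes are on that scale, which understates the change of low genes.

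The largest rise among genes meeting the naming rule was that of MTR_3g062880, from 0.649 ± 1.12 RPKM at 2 wpi to 102 ± 8.83 RPKM at 4 wpi (mean ± SD, n = 3). Its log2 change was 6.17 (SE 0.39, limma adjusted p = 2.94e-05). All of its 2 wpi signal was 20 reads in replicate 2, while the other 2 wpi libraries had 0 reads. Without replicate 2 the 4 wpi level was at least 335-fold higher, against a floor of 3 reads per library. MTR_0115s0030 rose from 8.28 ± 7.04 to 301 ± 43.1 RPKM (mean ± SD, n = 3), a log2 change of 5.26 (SE 0.43, limma adjusted p = 7.56e-05). Its 2 wpi values were 3.88, 16.4 and 4.57 RPKM in replicates 1, 2 and 3. With a pseudocount of 5 the order of the 2 loci turned, with log2 changes of 4.64 for MTR_0115s0030 and 4.26 for MTR_3g062880.

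The falls of MTR_2g040690 and MTR_3g034640 were the largest under the same rule and were close in size, and their order changed with the pseudocount, with TPM, with voom and with the library left out. MTR_2g040690 fell from 86.4 ± 12.3 RPKM at 2 wpi to 2.18 ± 0.12 RPKM at 4 wpi (mean ± SD, n = 3). Its log2 change was -4.77 (SE 0.12, limma adjusted p = 1.76e-06). MTR_3g034640 fell from 64.9 ± 1.35 to 1.46 ± 0.36 RPKM (mean ± SD, n = 3), a log2 change of -4.75 (SE 0.13, limma adjusted p = 2.16e-06). The deposited table pairs no identifier with a gene name, so the identity of these 4 loci is not given here.

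**Figure D2:**
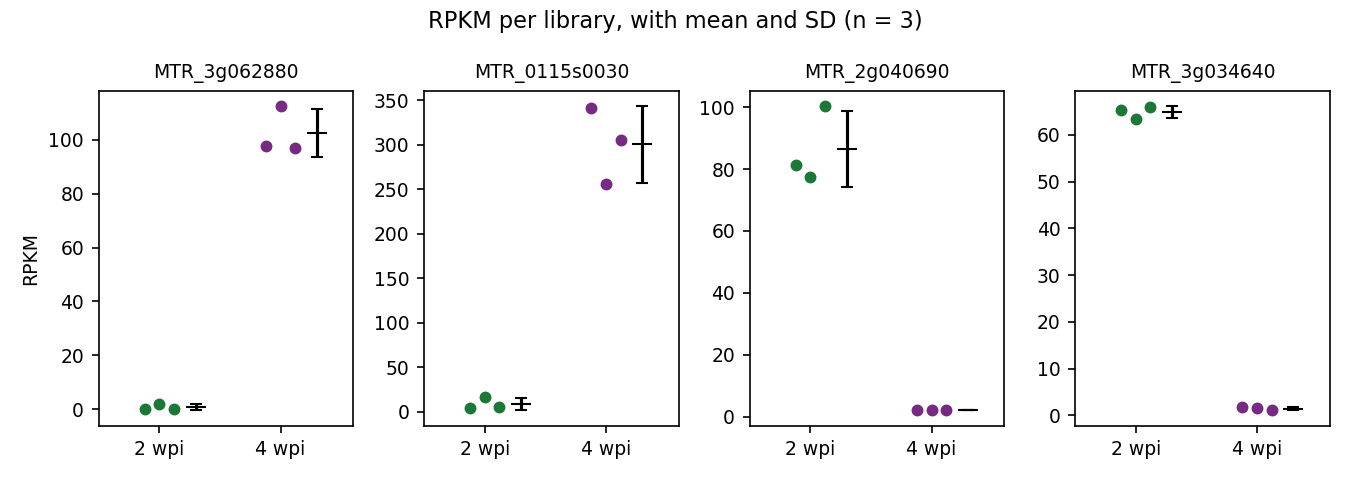
RPKM of MTR_3g062880, MTR_0115s0030, MTR_2g040690 and MTR_3g034640 in each library, with the mean and SD (n = 3) beside the points. In each panel the 3 libraries of one time point lie apart from those of the other, as the naming rule required. Replicate 2 is the highest 2 wpi library for both loci that rose.

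Loci written down as nodulation and symbiosis genes before the data were examined moved in both directions. Of 30 listed loci, 29 were tested, of which 10 rose, 13 fell and 6 did not pass (limma, adjusted over all genes tested). Adjusted over the list alone, 26 passed. Changes of at least 2-fold comprised 7 rises and 6 falls, and log2 changes ran from -1.62 to 2.19 with a median of -0.18. With TPM 10 rose and 14 fell, and with median-ratio factors 13 rose and 11 fell, so the larger of the 2 counts changed with scaling. By the words of the descriptions written beside the identifiers, a grouping chosen after the values were seen, 2 of 8 loci listed as transcription factors rose and 4 fell, and 2 of 6 listed as receptors rose and 3 fell. The list did not stand apart from other genes in net direction (limma camera, adjusted p = 0.453 with a preset correlation of 0.01). With an estimated correlation the adjusted p of camera was 0.815. Camera looks for a net shift, not for how often members changed in either direction. All but 6 of the 29 tested loci passed, a higher share than the 47.6% of all tested genes that passed, and this contrast was not tested. Camera placed the list above other genes whereas its median change lay below 0. The sign of that median was not stable, as it was 0.41 over the 25 loci left by a filter of at least 5 RPKM and 0.13 with the trend of change with gene length removed. With 1 list tested, adjustment left each p as it was. The fry test of limma gave an adjusted p = 0.186 for a net change downward and an adjusted p = 9.27e-07 for change in either direction, and neither compares the list with other genes. The identifiers in this list come from general knowledge and are not paired with names in the files, so these counts describe the listed identifiers. The loci held 0.255% ± 0.047 of summed RPKM at 2 wpi and 0.309% ± 0.017 at 4 wpi (mean ± SD, n = 3, 2-sided exact permutation p = 0.2, smallest possible 0.1). The difference was 0.0544 percentage points, and 0.0294 without 2 wpi replicate 1.

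Short genes rose more often than long genes, a grouping chosen after the data were seen. Of 698 genes under 300 bp, 41.0% rose at least 2-fold and 4.58% fell at least 2-fold. Of 3390 genes of 3000 bp or more, 1.62% rose and 5.75% fell by as much. The median log2 change was 0.58 in the shortest class and -0.28 in the longest, set against -0.16 over all tested genes. Rows with ENSRNA identifiers, the only other identifier form in the table, numbered 1328, of which 49 were tested, 17 rose and 2 fell.

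**Figure D3:**
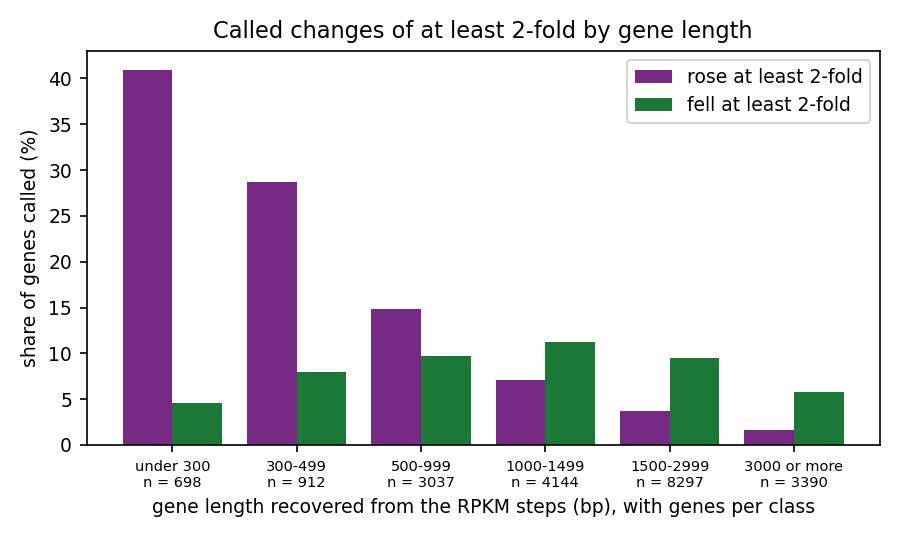
Share of tested genes called with a change of at least 2-fold (percent) in 6 classes of gene length (bp), with purple bars for rises, green bars for falls and the number of genes under each class. Rises make up 41.0% of the shortest class and 1.62% of the longest.

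A few genes held more of the signal at 4 wpi. The 100 most abundant genes of each library held 15.6% ± 0.42 of summed RPKM at 2 wpi and 18.4% ± 0.43 at 4 wpi (mean ± SD, n = 3, 2-sided exact permutation p = 0.1, the smallest possible). Genes with a value above 0 numbered 26228 ± 398 at 2 wpi and 25711 ± 422 at 4 wpi (mean ± SD, n = 3, 2-sided exact permutation p = 0.2). The first principal component held 85.5% of the variance and separated the time points. The 2 wpi libraries were spread along it, with scores of -84.4, -49.8 and -69.2 for replicates 1, 2 and 3, against 73.1, 68.7 and 61.6 at 4 wpi. Replicate 2 was thus the 2 wpi library nearest the 4 wpi libraries. Without it, 3698 genes changed at least 2-fold, with 1768 rises and 1930 falls.

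**Figure D4:**
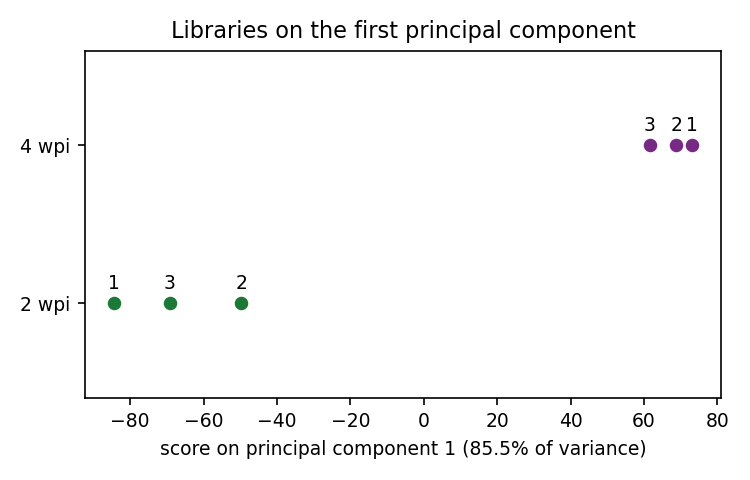
Score of each library on the first principal component of log2(RPKM + 1), with time points on separate lines and replicate numbers above the points. The 2 wpi libraries lie between -84.4 and -49.8 and the 4 wpi libraries between 61.6 and 73.1.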

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

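The length-trend, voom and abundant-gene alternatives and the share of the 100 most abundant genes were chosen after seeing the data. Apart from the 2-fold threshold, 20 alternatives gave 7925 to 11664 changed genes, 2566 to 4749 higher and 4425 to 9098 lower, each within 1.5 times the reported count. Requiring a 2-fold change left 3536 genes, 1669 higher and 1867 lower, by the construction of the threshold. Leaving out each library in turn gave 8139 to 9077 changed genes, 2822 to 3220 higher and 5286 to 5857 lower. Voom on recovered reads called 10197 genes, and 9377 of the 9712 calls with resolved reads were called there too. Removing the length trend left 8735 calls, of which 49.3% were higher, and 7357 of the original calls were among them. The replicate block gave 8740 calls (3106 higher and 5634 lower), 8554 of them shared. The main fit had no block, as fixed beforehand, since no label says that the numbers pair the libraries. Same-numbered libraries did not deviate together (correlations across genes of -0.06, 0.03 and -0.05). Only 2 wpi replicate 2 correlated best with its own number. With 3 libraries per time point, these values cannot exclude pairing. The list of 30 identifiers missed the threshold for a net shift in each of 22 alternatives. The fry test of limma gave the reversed direction (median -0.18, adjusted p = 0.186 over 1 list). By construction it sets the list against 0, whereas camera sets it against other genes. The medians do not account for the reversal, as that of the list lay below that of all tested genes (-0.176 against -0.155). Leaving out each library gave list medians from -0.34 to -0.06, but the median was above 0 with a filter of at least 5 RPKM (0.41, 10 rose and 10 fell) and with the length trend removed (0.13, 12 rose and 11 fell). All 4 named loci kept their direction and passed in 20 alternatives each. The log2 change of MTR_3g062880 ranged from 4.26 with a pseudocount of 5 to 9.21 with voom, because its 2 wpi level rests on 20 reads. The planned scaling without leghemoglobins and NCR peptides, the 35 lists based on descriptions and the test of rhizobial genes were not run, for lack of gene names.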

Other observations

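All tests in this part were chosen, and their bounds set, after the related values had been seen, so they can argue against an explanation but do not establish one. The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of the 10 splits, the real one, gave as many as 9829 genes. The highest of the other splits gave 0. Each of those mixes libraries of both time points within a group, so the difference between time points widens the spread there. Low counts in them were therefore built in. With 10 splits the share cannot fall under 0.1, so the design is too small for this count to reach 0.05.

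Genes under 500 bp rose at least 2-fold more often than genes of 1500 bp or more (34.5% against 3.12%, called or not). A length bias of the libraries is one candidate explanation. The running median change at each length was then removed. The share in short genes was still 6.92 times that in long genes (95% bootstrap interval 6.23 to 7.79). A wider spread of changes in short genes could keep this ratio high, and falls after the removal were not counted. Counting noise alone would send short genes both ways. However, called 2-fold rises outnumbered falls 5.22 to 1 (548 against 105, 95% exact interval of the ratio 4.23 to 6.49). These calls were made before the length trend was removed, so a trend and noise acting together are not argued against. Both intervals, like the bootstrap intervals below, treat genes as independent and do not measure the spread between libraries. A change in nodule age also remains open and untested, as the time points differ in age by design.

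Replicate 2 of 2 wpi lay nearest the 4 wpi libraries, and RNA of 4 wpi nodules mixed into it could place it there. A single mixing fraction should then serve rising and falling genes, but the median fraction was 6.37% in 200 rising and 11.7% in 170 falling genes, a difference of 5.35 percentage points with overlapping 95% bootstrap intervals. With the roles of replicates 1 and 3 exchanged it was 6.0% in 92 and 19.9% in 138 genes, with intervals apart, so mixing cannot be told apart from other causes because the result depends on the baseline. A cleaner test, on genes with at most 3 reads in replicates 1 and 3 together and at least 300 at 4 wpi, was void because 1 gene met it. The 2 wpi libraries may instead differ in progress along the same change, since differences between them followed the change measured against the remaining 2 wpi replicate, with r = 0.516 (replicate 2 minus 1), 0.394 (2 minus 3) and 0.242 (3 minus 1) across genes, which are not independent replicates. The same pairs at 4 wpi gave -0.045, 0.164 and -0.183, and as the values had been seen before the bound was set and the pair without replicate 2 lay nearest the 4 wpi sizes, the question stays open.

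Tested loci that followed each other in identifier number changed together. These are called neighbours here, although untested loci can lie between them. Over 20105 tested loci with a numbered identifier, neighbouring log2 changes correlated with r = 0.266 across genes, against -0.019 to 0.023 in 1000 shuffles within chromosome number, so a chance order of loci is not a likely cause. Of 437 loci with a called log2 change of at least 3, 168 (38.4%) stood next to another such locus, against at most 45 in the shuffles. Reads shared between neighbouring copies remain open, since sequence was not used here, and no biological explanation was tested.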
